A study of Salmo salar with 24 samples.

How the data were processed

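Liver RNA of Atlantic salmon (Salmo salar) was measured on 2-colour oligonucleotide arrays of 43689 probes, 1 array per fish. The 24 fish came from 3 diets, with 4 tanks per diet and 2 fish per tank. Every fish was labelled with Cy5, and a pool of liver RNA was labelled with Cy3 as common reference, per the labels. Their protocol describes a pool of the fish measured here, while the source name of the pool mentions other diets, so what a single ratio is relative to stays unsettled. Differences between diets do not depend on it, because all arrays share the reference. No dyes were swapped, so a dye effect that differs between probes is shared by all arrays and drops out of differences between diets, but not out of single ratios. Diet was given to tanks, so the tank is the unit that received the treatment.

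The deposited scanner tables hold the intensity of each of 45220 spots in both channels on a linear scale, with the local background not yet subtracted. Image quantification used software of version 9.0, per the file headers, and the scanner settings are not given in the sources used here. A quality code per spot was set by that software, per the file headers. Spots coded as marked by hand or as poor were left out here, except poor spots whose only failure was saturation. Spots with any other code were kept. A second deposited table holds log2 ratios of Cy5 over Cy3 for the same arrays. It was set against median pixel signals of the scanner, not the mean signals used below. The authors' column for each array had a slope of 0.999 to 1.00 and a correlation of at least 0.99984 across probes once a trend with intensity was removed, and at least 0.941 without that step. The trend was fitted to the difference from the authors' own column, so the match after that step is partly built in. Scale and direction of that table were thereby settled as log2 of fish over reference. Its column medians ran from -0.03 to 0.07, so the columns lay close to 0, but how the authors removed the trend is not given in the sources used here. Between 63.6% and 76.3% of the entries in a column were blank, and only spots with a quality code of 0 had a value.

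Mean foreground and median background intensities were corrected with normexp and an offset of 50 in limma 3.58.1 under R 4.3.3. Each array was then normalised with a global loess, in which the 1531 control spots and left-out spots had weight 0. A probe was kept if it had values from at least 4 fish of every diet, which held for 40918 probes. It was tested if its Cy5 signal also exceeded the local background by 2 SD of that background on at least 6 of the 8 arrays of a diet. This left 38748 probes. The filter was lenient, because 73.9% to 98.7% of the negative control spots of an array also passed the same limit for a single spot. A stricter limit, the mean plus 2 SD of the negative control spots, was passed by 15298 of the tested probes (39.5%). Between 4.75% and 12.7% of the spots of an array were left out for their quality code. Saturated spots made up 1.38% to 2.38%, and those without another failure were kept. The number of arrays limits the precision of each value.

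Diets were compared with limma (lmFit and eBayes) on log2 ratios in 1 fit of all 24 arrays, with the tank as a random block. The estimated correlation within tanks was -0.05 and was set to 0, as fixed in advance for a negative estimate, so the main values equal those without a block. They therefore treat the 2 fish of a tank as independent. The fish of a tank always lay on different slides, and arrays that shared a slide were alike. The estimate thus does not show that tanks had no effect. Each of the 3 pairwise comparisons, a moderated F test over the diets and a slope on the number in the diet's name had a Benjamini-Hochberg adjustment over the probes tested, and all of these tests were 2-sided except the F test. A probe was called at an adjusted p under 0.05, with 0.10 as the alternative. The groups, tests, the rule for naming items and most alternatives were fixed before the data were examined. In fits with a slide, scan or position block, limma approximates the standard errors of contrasts where spots are missing. The rank product test was run as the other tool, on all pairs of arrays of the diets compared, with 100 permutations and an estimated share of false calls under 0.10.

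Data were simulated as independent normal values with the moderated spread of the real probes, and 200 of 38748 probes were changed. They held no slide or tank structure and no correlation between probes. The change was added to ratios after the offset, where a dim probe shows less of a true change. Recovery in the real data may therefore be lower. In these simulations limma recovered 155 of the probes changed 2-fold and 8 of those changed 1.5-fold for ω3LC1.4 against ω3LC0. It recovered 163 and 4 for ω3LC1 against ω3LC0, and 152 and 6 for ω3LC1.4 against ω3LC1. At 3-fold it recovered 197, 197 and 198. False calls at 2-fold numbered 5, 8 and 13. In the same simulations at 2-fold, the rank product recovered 182, 176 and 174 of the 200 probes, with 238, 217 and 231 false calls.

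No probe carried a gene name in the deposited tables. Of the probes, 409 were listed by an accession, and 0 of these matched the gene table used here, which is built on the assembly Ssal_v3.1. Probes are therefore given by their position on the array. The rule for naming items allowed, without gene names, at most 2 probes that were higher and 2 that were lower in each pairwise comparison. Those with the highest and the lowest moderated t statistic were taken, and none of them passed the threshold. The 26 gene lists fixed in advance had no measured members by name, so no list was tested.

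Alternatives covered background correction, normalisation within and between arrays, filters, quality codes, the tank, the slide, the scan, array weights, thresholds, the rank product, the authors' ratios, the fish numbers as a block and each tank left out in turn. A loess per print block was not run, since the tables give a single block. Others were added after the data had been seen. These were median pixel signals, the limit from negative control spots, the position of the array on its slide, subsets of slides and scans, the removal of 2 arrays with low reference signal, and the rank product on other values. The highest correlation of log2 ratios between any pair of arrays was 0.406, so no array was a repeat of another.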

Results

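The livers of juvenile Atlantic salmon were profiled for diets named ω3LC0, ω3LC1 and ω3LC1.4. The labels give 14 weeks of feeding and sampling at week 16, with the difference not explained in the sources used here. The series title describes a question about dietary DHA and EPA, long-chain omega-3 fatty acids that salmon obtain mainly from marine ingredients. The numbers 0, 1 and 1.4 in the diet names carry no unit in the labels. Each diet was fed in 4 tanks, and 2 fish per tank were measured, so that n = 8 fish per diet unless a smaller n is given where spots were left out. The fish weighed 178 g on average at the start.

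The median Cy5 signal of an array ran from 87.4 to 390 and the median Cy3 signal from 116 to 385. Between 80.3% and 95.9% of the spots of an array exceeded their local background in the Cy5 channel. The typical SD between fish of a diet was 0.37 on the log2 scale (median over the 38748 probes tested). Every slide held all 3 diets, but diet followed the position of the array on the slide. Position 1 held 6 ω3LC1 arrays, and position 4 held 6 ω3LC1.4 arrays. Position 2 held 4 ω3LC0 and 2 ω3LC1 arrays, and position 3 held 4 ω3LC0 and 2 ω3LC1.4 arrays. Both fish of a tank lay at the same position, on different slides. The median Cy5 signal was 275 ± 67.5 on slides 1 to 3 and 134 ± 39.5 on slides 4 to 6 (mean ± SD, 12 arrays each).

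**Figure D1:**
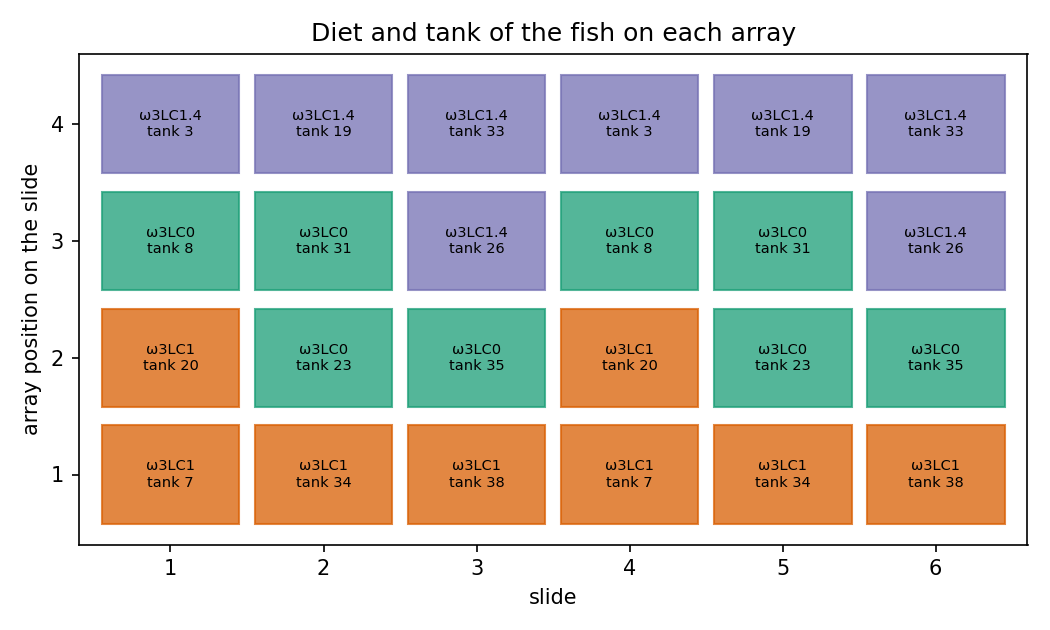
Slide (horizontal axis) and position on the slide (vertical axis) of the 24 arrays, with the diet as colour and the tank as text. All 6 arrays at position 1 were ω3LC1 and all 6 at position 4 were ω3LC1.4.

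The comparison of ω3LC1.4 with ω3LC0 set the highest label number against the lowest. No probe was called at an adjusted p under 0.05 or 0.10 in limma, and the smallest adjusted p was 0.346. At an unadjusted p under 0.05 there were 2747 probes, 1453 higher and 1294 lower in ω3LC1.4, where 1937 would be expected if nothing differed. With median in place of mean pixel signals, 742 of 2283 were higher. The 95% confidence interval of the difference, for ratios after the offset, lay within 2-fold for 95.7% of the probes and within 1.5-fold for 56.3%. Since a dim probe shows less of a true change after the offset, these intervals do not bound the true change of dim probes. The rank product test called 222 probes, 126 higher and 96 lower in ω3LC1.4, and 87.8% of these were among the 10% of probes with the largest SD between fish.

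Probe C005R107 had a log2 ratio of 0.54 ± 0.26 (SD, n = 7) in ω3LC1.4 and -0.42 ± 0.50 (SD, n = 7) in ω3LC0, a difference of 0.96 with a standard error of 0.19. Probe C024R094 was 0.76 higher (SE 0.15) in ω3LC1.4. Probe C070R018 differed by -0.80 (SE 0.16), and C059R036 by -1.15 (SE 0.25). The limma adjusted p of each was 0.346, and none passed the threshold. The difference from the ω3LC0 mean had the same direction in 7 of 7, 8 of 8, 7 of 7 and 7 of 8 ω3LC1.4 fish, as picking probes by their statistic favours. With median pixel signals the differences were 0.10, 0.03, -0.38 and -0.75 in the same order, and with plain background subtraction C005R107 was at 0.06, C024R094 at 1.98 and C070R018 at -1.48. With array position as a block, a fit in which the difference rests on the 1 ω3LC1.4 tank that shared a position with ω3LC0, C059R036 was at -0.72. The first 3 of these probes were dim, with median Cy5 signals of 61.7, 79.5 and 73.4, and exceeded the limit set by the negative control spots on 0 of 24 arrays. C059R036 was bright, at a median of 5390 and over that limit on 23 arrays, but exceeded its own local background on only 3 of 8 ω3LC1.4 arrays, so its ω3LC1.4 level is uncertain. Leaving out ω3LC1.4 tank 26 gave 2 calls, C012R111 and C266R081, which are named after their values were seen. Their differences were then 2.14 and -2.33, against 1.58 and -0.93 with all tanks, at median Cy5 signals of 133 and 78.7.

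The comparison of ω3LC1 with ω3LC0 gave a similar number of probes at an unadjusted p under 0.05, but fewer far below that limit. No probe was called at an adjusted p under 0.05 or 0.10 in limma (smallest adjusted p 0.338). At an unadjusted p under 0.05 there were 2797 probes, 1168 higher and 1629 lower, against 1937 expected. No excess was left with median pixel signals (1937, 795 higher) or without ω3LC0 tank 31 (1885, 882 higher). Under median centring in place of loess 694 of 2372 were higher, and with array position as a block, resting on 1 ω3LC1 tank, 1067 of 2085 were. The 95% confidence interval, again for ratios after the offset, lay within 2-fold for 95.8% of the probes and within 1.5-fold for 56.5%. The rank product test called 176 probes, 54 higher and 122 lower in ω3LC1, and 94.9% of these were among the 10% with the largest SD between fish.

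Probe C140R018 had a log2 ratio of -0.62 ± 0.64 (SD, n = 8) in ω3LC1 and 0.91 ± 0.79 (SD, n = 7) in ω3LC0, a difference of -1.53 with a standard error of 0.28 and a limma adjusted p of 0.338. Probe C210R030 differed by -0.95 (SE 0.20, adjusted p = 0.470). Both were dim, with median Cy5 signals of 99.9 and 51.2. Probe C078R151 was 0.73 higher in ω3LC1 (SE 0.14, adjusted p = 0.438), at a median Cy5 signal of 338, and exceeded the limit set by the negative control spots on 11 of 24 arrays. Probe C089R107 was 0.78 higher in the fit (SE 0.17, adjusted p = 0.470), at a median signal of 1102. It was above local background on 0 of 8 ω3LC0 arrays and 6 of 8 ω3LC1 arrays, but over the limit set by the negative control spots on 22 of 24 arrays, so its ω3LC0 level is uncertain rather than absent. In the Cy5 channel alone, which held the fish of both diets, the means of the normalised signal differed 2.09-fold, against 1.72-fold in the ratios. Neither is a lower bound, because the lowest signal above background lay under the probe's own signal on the ω3LC0 arrays. None of these 4 probes passed the threshold. The direction was shared by 8 of 8 ω3LC1 fish, and by 6 of 6 for C210R030, as picking probes by their statistic favours. With array position as a block the difference was -0.54 for C140R018 and -0.62 for C210R030. With median pixel signals C210R030 was at -0.33, and within slides 4 to 6 at -0.30. Plain background subtraction gave -2.37 for C140R018 and -1.87 for C210R030, and no background subtraction gave 0.46 for C089R107.

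The comparison of ω3LC1.4 with ω3LC1 set the diets of the higher label numbers against each other. No probe was called at an adjusted p under 0.05 or 0.10 in limma (smallest adjusted p 0.438). At an unadjusted p under 0.05 there were 2434 probes, 1424 higher and 1010 lower, against 1937 expected. With median pixel signals, 913 of 2086 were higher, so that the balance turned, and without ω3LC1.4 tank 33 no excess was left (1733, 1012 higher). The 95% confidence interval, again for ratios after the offset, lay within 2-fold for 95.8% of the probes and within 1.5-fold for 58.2%. The rank product test called 270 probes, 178 higher and 92 lower in ω3LC1.4, and 90.7% of these were among the 10% with the largest SD between fish.

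Probe C192R019 had a log2 ratio of -0.74 ± 0.43 (SD, n = 8) in ω3LC1.4 and -2.30 ± 0.99 (SD, n = 6) in ω3LC1, a difference of 1.56 with a standard error of 0.32. Probe C013R165 was 0.83 higher in ω3LC1.4 (SE 0.17). Probe C224R073 differed by -0.81 (SE 0.16), and C059R036, the same bright probe that was among the lowest against ω3LC0, by -1.16 in the fit (SE 0.24), with the uncertain ω3LC1.4 level noted above. The limma adjusted p of each was 0.438, and none passed the threshold. The direction was shared by 8 of 8, 6 of 6, 8 of 8 and 7 of 8 ω3LC1.4 fish, as picking probes by their statistic favours. With array position as a block C192R019 was at 0.68 and C059R036 at -0.48. C013R165 was at 0.11 with median pixel signals and 3.26 with plain background subtraction, and within slides 1 to 3 C192R019 was at 0.80 and C224R073 at -0.50. Median Cy5 signals were 310 for C192R019, 54.6 for C013R165 and 1052 for C224R073. The limit set by the negative control spots was exceeded on 11, 0 and 22 of 24 arrays in the same order. With median centring in place of loess, 12 probes were called, 7 of them higher in ω3LC1.4, and C013R165, C224R073 and C059R036 were among them. The 7 higher ones had median Cy5 signals of 48.2 to 118, and the lower ones of 577 to 5390. Without ω3LC1.4 tank 26, 3 probes were called, C012R111, C266R081 and C059R036, the first 2 named after their values were seen.

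**Figure D2:**
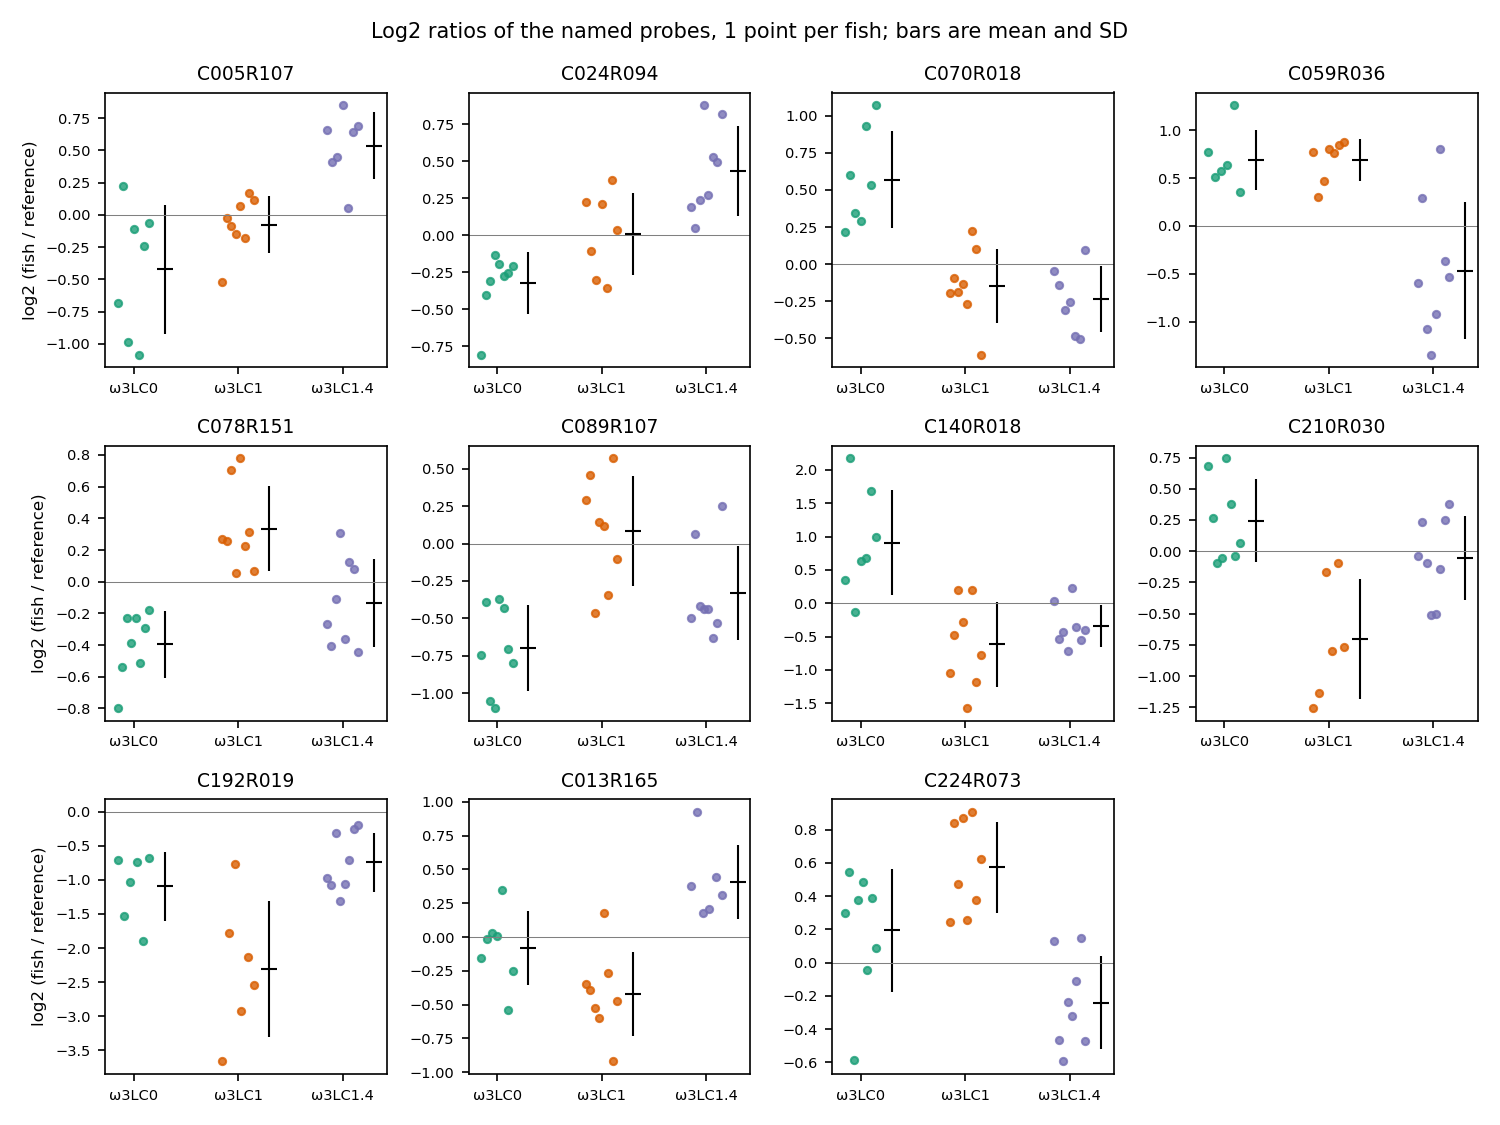
Log2 ratio of fish over pooled reference (vertical axis) for the 11 named probes in each diet (horizontal axis), with 1 point per fish and bars for mean and SD. C059R036 had a mean of -0.47 in ω3LC1.4 with an SD of 0.71, against 0.69 in both other diets.

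The F test asked whether any diet differed from another, and the slope asked whether probes followed the number in the diet name. The F test called no probe in limma (smallest adjusted p 0.540), with 2789 probes at an unadjusted p under 0.05. The slope also called no probe in limma (smallest adjusted p 0.344), with 2789 probes at an unadjusted p under 0.05, 1370 rising and 1419 falling with the number. The rank product compares only pairs of diets and gave the 222, 176 and 270 calls above. On the means of the 2 fish of each tank, limma called 0 probes in the 3 pairwise comparisons, the F test and the slope. At an unadjusted p under 0.05 there were then 3042, 3025, 2548, 3151 and 3003 probes. With the slide as a block, limma called 0 probes in each of these 5 tests, with 3053, 3323, 2574, 3320 and 3039 probes at an unadjusted p under 0.05. A single slide held at most 2 arrays of a diet, too few for a value within each slide. Within slides 1 to 3, with 1 fish per tank, limma called 0 probes in the 3 pairwise comparisons, and 1663, 3353 and 1932 had an unadjusted p under 0.05. Within slides 4 to 6 it also called 0, with 3066, 1267 and 3478 at an unadjusted p under 0.05.

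**Figure D3:**
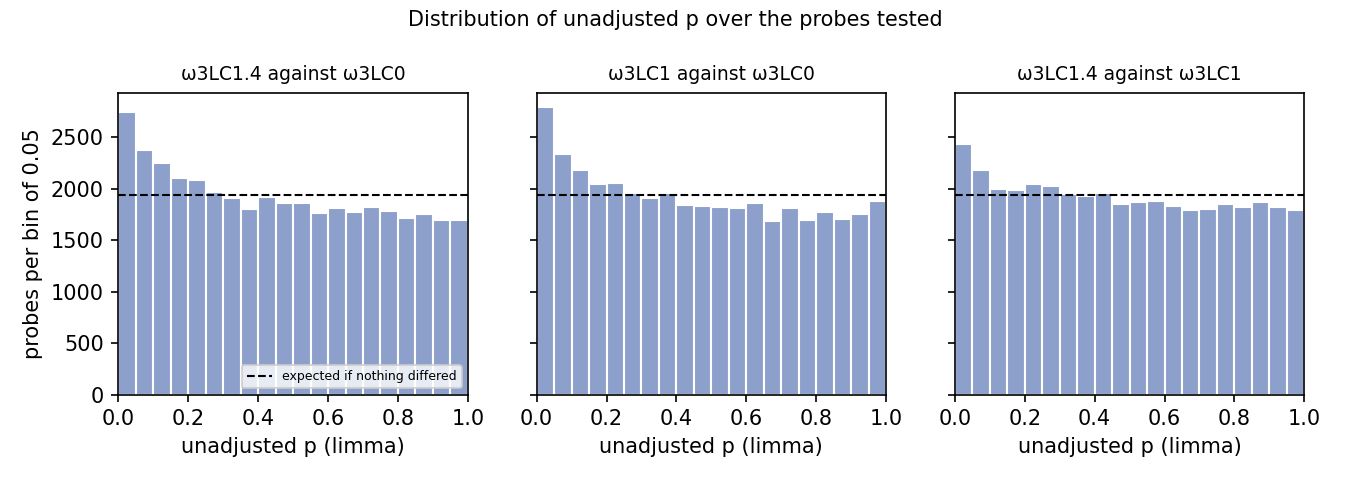
Number of probes (vertical axis) per interval of 0.05 in unadjusted p (horizontal axis) for the 3 pairwise comparisons, with a dashed line at the 1937 expected if nothing differed. The lowest interval held 2747, 2797 and 2434 probes.

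The log2 differences of ω3LC1.4 and of ω3LC1 against ω3LC0 had a correlation of 0.520 across probes, which are not independent replicates. Both share the 8 ω3LC0 fish, and unchanged groups sharing them gave 0.497 on average in 1000 simulated draws (95% of draws from 0.326 to 0.651). With the ω3LC0 tanks divided so that each comparison had its own, the correlation was 0.0778 on average (0.0356 to 0.121 over the divisions). The covariance was 0.0292, against 0.0244 in the simulation and 0.00616 with divided controls. The observed correlation and covariance lay within the simulated ranges, and 180 of the 1000 draws had a covariance as high. Under median centring the correlation was 0.107 and the covariance 0.0104.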

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

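The splits of the counts at adjusted p, those within slides or within an array position, the fits by array position and the split by slides were chosen only after the counts were seen, while the other tests of this part were set before their results were known. Of 54 groups of values examined, 2 had a fish far from the rest. Chance flags about 1 in 20 groups. Probe C024R094 in ω3LC0 had replicate 1 at -0.81 and the next fish at -0.40, so that the gap took 0.601 of the range of the 8 fish. Probe C013R165 in ω3LC1.4 had replicate 2 at 0.93 and the next fish at 0.45, so that the gap took 0.642 of the range of the 6 fish with a value. Both fish lay on the side that widened the difference for which the probe was named, and both probes stayed under the limit of the negative control spots on all 24 arrays.

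Splits of the fish into groups of the same sizes, the diets included, gave the following for counts at an unadjusted p under 0.05. As many probes as between ω3LC1.4 and ω3LC0 (2747) came from 2 of 100 splits, with 3153 as the highest other. As many as between ω3LC1 and ω3LC0 (2797) came from 3 of 100, with 2925 as the highest other. Such counts were thus rare among splits of fish for both, although single other splits gave more probes. Between ω3LC1.4 and ω3LC1 (2434), 15 of 100 gave as many, with 3707 as the highest other. For the F test 8 of 100 groupings gave as many (2785 in the refit used for the splits, highest other 3789), and for the slope 8 of 100 (2789, highest other 3198), which does not exclude chance. These splits moved fish freely over slides, by which arrays were alike. With diets moved only within slides, 2 of 100 splits gave as many for ω3LC1.4 against ω3LC0 (highest other 2798) and 2 for ω3LC1 against ω3LC0 (highest other 3071). For the F test it was 1, the diets themselves (highest other 2635), and for the slope 3 (highest other 2895). For ω3LC1.4 against ω3LC1, 6 of 100 gave as many (highest other 2660), and chance could not be excluded by either count. All these splits, free or within slides, took the 2 fish of a tank as independent, although diet was given to tanks. Low shares therefore do not exclude a chance allocation of tanks. Whole tanks were not regrouped for the F test or slope counts. At adjusted p the real counts from limma were 0 in all 5 tests, which 100 of 100 splits reach by definition, and the highest other splits gave 1, 2 and 7 calls in the pairwise comparisons in the order above, 1 in the F test and 0 for the slope. The rank product calls for the same comparisons were 222, 176 and 270.

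A split of the arrays by slides, 1 to 3 against 4 to 6, gave 54 probes at a limma adjusted p under 0.05 among the ω3LC1 and ω3LC0 arrays, and 3707 at an unadjusted p under 0.05, more than the diets. Among the ω3LC1.4 and ω3LC1 arrays it gave 0 at adjusted p and 2686 at an unadjusted p under 0.05, more than the diets, and among the ω3LC1.4 and ω3LC0 arrays 0 and 2468, fewer than the diets. The 54 probes point to a structure among the ω3LC1 and ω3LC0 arrays that follows slides or scans, since 7 of their 8 arrays on slides 1 to 3 were of scan 2 and all 8 on slides 4 to 6 of scan 1, so that neither is favoured. With the slide as a block limma called 0 probes in the 3 comparisons, and 3053, 3323 and 2574 had an unadjusted p under 0.05 (ω3LC1.4 against ω3LC0, ω3LC1 against ω3LC0, ω3LC1.4 against ω3LC1). The smallest limma adjusted p in that fit were 0.313, 0.0725 and 0.0942 in the same order.

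The first pattern weighed is the excess of probes at an unadjusted p under 0.05 over the 1937 expected. When whole tanks were regrouped, 1 of 35 splits gave as many probes for ω3LC1.4 against ω3LC0 (highest other 2630) and 1 of 35 for ω3LC1 against ω3LC0 (highest other 2742), the diets themselves. This is the smallest share that 35 splits can give, without adjustment over the 3 comparisons. It makes chance unlikely by this count in the main processing, but does not exclude it. For ω3LC1.4 against ω3LC1, 3 of 35 gave as many (highest other 2532), which leaves chance open. These splits moved tanks freely over slides. In ω3LC1 against ω3LC0 no excess was left with median pixel signals (1937) or without ω3LC0 tank 31 (1885), so that this excess depends on the processing and on 1 tank. Array position was tested within ω3LC0, where position 3 against position 2 gave 1830 probes and 17 of 35 splits of these 8 arrays gave as many (highest other 2510), and a steady gradient by the covariance of the comparisons against ω3LC0, which was 0.0292, with 180 of 1000 simulated draws at or above it and 820 at or below. With position as a block the counts were 2932 for ω3LC1.4 against ω3LC0 and 2085 for ω3LC1 against ω3LC0, and within the position that held both diets 2681 (2 of 15 splits of the arrays gave as many, highest other 3049) and 1986 (5 of 15, highest other 3192). The 2 arrays of ω3LC1.4 or ω3LC1 in such a position came from 1 tank, and these splits took fish of a tank as independent, so that the counts by position decide nothing and both diet and position stay open.

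The other pattern weighed here is the calls of the rank product where limma made none. Regrouping whole tanks, with 10 permutations each, gave as many calls in 1 of 35 splits for ω3LC1.4 against ω3LC0 (226, highest other 214) and in 1 of 35 for ω3LC1.4 against ω3LC1 (248, highest other 218), but in 11 of 35 for ω3LC1 against ω3LC0 (179, highest other 319), where chance could not be excluded. A candidate explanation for most calls is that the probes that vary most between fish rank at the ends under any grouping. The median over the other splits was 139.5, 145 and 130 calls (ω3LC1.4 against ω3LC0, ω3LC1 against ω3LC0, ω3LC1.4 against ω3LC1), and in simulated data for ω3LC1.4 against ω3LC0 with nothing changed the test made 161 calls when each probe had its own spread and 0 when all had the same. A diet effect on part of the called probes stays open for the comparisons with ω3LC1.4.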

How the results depend on the processing

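The alternatives on array position, scan and slide subsets, negative control spots, median pixels, arrays of low reference signal and the rank product on other values were chosen only after the data were seen. No probe was called in 36 of 42 alternatives for ω3LC1.4 against ω3LC0, 39 of 42 for ω3LC1 against ω3LC0, 34 of 41 for ω3LC1.4 against ω3LC1, 32 of 36 for the F test and 36 of 36 for the slope. The smallest limma adjusted p ran over them from 0.000762 to 1.00, 0.0660 to 1.00, 0.00541 to 1.00, 0.00102 to 0.984 and 0.0685 to 1.00. Of 413 values of named probes, 0 reversed and 4 came to pass the threshold, for ω3LC1.4 against ω3LC1: C013R165, C224R073 and C059R036 under median centring, and C059R036 without ω3LC1.4 tank 26. Some almost vanished: C005R107 ran from 0.06 to 1.39, C024R094 from 0.03 to 1.98 and C013R165 from 0.11 to 3.26. Others became smaller: C140R018 ran from -2.37 to -0.54 and C059R036 against ω3LC1 from -1.66 to -0.48. Aquantile scaling leaves ratios unchanged by construction, and the fit without a tank block equals the main one. A fold limit added to the threshold can only remove calls. These alternatives are counted above but could not add a call. Loess per print block and the gene list alternatives were not run.

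Median centring without loess called 12 probes for ω3LC1.4 against ω3LC1, 7 higher, and 1 in the F test (C059R036), and gave a correlation of 0.107 for the comparisons against ω3LC0. Counts at an unadjusted p under 0.05 became 6065 (2997 higher), 2372 (694 higher) and 10435 (5350 higher) in the pairwise comparisons in the order above and 7862 in the F test. Before loess, log2 ratios changed with log2 intensity by -0.11 ± 0.13 in ω3LC1.4, -0.01 ± 0.08 in ω3LC0 and 0.02 ± 0.06 in ω3LC1 (SD, n = 8), a trend that loess removes by construction. Divided ω3LC0 tanks gave a correlation of 0.0778.

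The rank product called 222, 176 and 270 probes in the same order, 87, 107 and 158 on the authors' deposited ratios (12872 probes), and 176, 146 and 221 on the 15298 probes over the negative control spots. Array position as a block, in which the differences from ω3LC0 rest on 1 tank of ω3LC1 or ω3LC1.4, gave 2 calls for ω3LC1.4 against ω3LC0 (C027R026, C141R001) and 3 in the F test (also C097R111). Arrays of scan 1 alone gave 1 for ω3LC1.4 against ω3LC0 (C257R081), 2 for ω3LC1.4 against ω3LC1 (also C188R163) and 1 in the F test (C257R081). Leaving out each tank in turn gave 0 to 2, 0 to 0 and 0 to 3 calls, 0 to 3 in the F test and 0 to 0 for the slope. All came without ω3LC1.4 tank 26 and were C012R111 and C266R081, joined by C059R036 for ω3LC1.4 against ω3LC1 and in the F test. Probes other than C059R036 were named after their values were seen, and the cause was not tested.

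The fish numbers of the titles were not taken as pairs: correlations of same-numbered fish ran from -0.11 to 0.19 and 7 of 24 pairs were over 0.1. Of the 24 fish, 7 matched their own number best, where chance gives 3 if slides are ignored. However, each of the 7 pairs over 0.1 shared a slide, and 4 of the numbers lay on 1 slide in all diets. Arrays that shared a slide were alike, so these matches are no separate sign of pairs. With the number as a replicate block, 1 probe was called for ω3LC1.4 against ω3LC1 (C005R082, -1.71, named after its value was seen). Signal over background is a limit, since only 39.5% of the tested probes exceeded the negative control spots.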

Other observations

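The test of array position on tank means and the groupings within slide pairs were chosen only after the result for diet was seen, and the other tests of this part were set before theirs were known. Deviations of the fish from their diet means were compared between arrays over all probes. Arrays that shared a slide but not a diet had a mean correlation of 0.0792 (30 pairs), against -0.0148 for arrays sharing neither slide nor tank nor diet (162 pairs). The difference was 0.0940, with a permutation p of 1e-04 (one-sided, 10000 reshuffles of slides within diets), the smallest these reshuffles can give. Fish of the same tank had a mean correlation of -0.177 (12 pairs) and fish of the same diet from other tanks -0.141 (72 pairs), where values below 0 follow from taking deviations from the diet mean. The permutation p for the tank was 0.895 (one-sided). The fish of a tank always lay on different slides, so likeness within tanks could be hidden, and this test does not exclude a tank effect.

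The last pattern weighed is that the 12 tank means differed between diets over the whole array, although no single probe passed the threshold in limma. Diets took up 21.3% of the variance of the tank means over 35744 probes, and 31 of all 5775 groupings of the tanks into 3 sets of 4 gave as much (exact permutation p = 0.00537, one-sided), against a median of 18.1% over the groupings. Array positions took up 29.2%, and 1198 of all 15400 groupings into 4 sets of 3 gave as much (exact permutation p = 0.0778, one-sided), against a median of 27.2%. These groupings moved tanks freely over slides, although arrays that shared a slide were alike and the tanks lay in slide pairs (1 and 4, 2 and 5, 3 and 6). With labels moved only among the tanks of a slide pair, 1 of all 1728 groupings gave as much for diets, the diets themselves (exact permutation p = 0.000579, one-sided, median 17.6%), and 2 of all 576 for positions (exact permutation p = 0.00347, one-sided, median 26.1%). By these counts chance is unlikely in the main processing, the only one in which this was tested, but it is not excluded. Within slide pairs both labels pass, and they largely overlap. A small diet effect spread over many probes is a candidate explanation, and a position effect stays open beside it, because only 2 of the 8 arrays of ω3LC1 and of ω3LC1.4, each time from 1 tank, shared a position with another diet. The principal components of the log2 ratios were spread thinly, the first 3 taking 10.6%, 9.09% and 7.16% of the variance over 20003 probes.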
